A study of Homo sapiens with 12 samples.

How the data were processed

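Gene expression was measured in A549 cells, an established human lung adenocarcinoma line widely used as a model of alveolar epithelium. Per the series design text and the labels' protocols, the cells were seeded on permeable inserts 24 h before exposure and were exposed for 4 h to diluted aerosol from burning beech logs or wood pellets. Inserts exposed to clean air at the same time served as the reference. There were 3 exposures per fuel, and in each 3 inserts received the aerosol and 3 received clean air. The labels give 4 groups of 3 samples: beech aerosol, beech clean air, pellet aerosol and pellet clean air. The labels do not say whether the 3 inserts of an arm were pooled before RNA extraction, and p-values of single genes here measure the spread between these exposures.

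Per the labels' protocols, 100 ng of total RNA per sample was labelled with Cy3 and hybridised to 1 Agilent one-colour array. Per the file headers and the submitters' processing notes, the authors scanned the arrays with Agilent Feature Extraction 11.0.1.1. Each deposited scanner file gives, per spot, a processed signal, which is a fluorescence intensity corrected for background within the array, per the file headers. The deposited value table of the series holds the same intensity in rounded form. Its ratio to the processed signal of the same spot lay between 0.995 and 1.005 on every array, its scale was linear, and no centring or scaling between arrays was visible. The column medians of that table ran from 118 to 197. Each array held 62976 spots, of which 58717 were not controls and represented 42405 distinct probes.

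The arrays lay on 3 slides. Slide 1 held the 3 pellet aerosol arrays and pellet clean-air replicates 1 and 2, slide 3 held the 3 beech aerosol arrays and beech clean-air replicates 1 and 2, and slide 2 held clean-air replicate 3 of each fuel. The files of slide 2 had 25 columns and the others 61. The 75th percentile of the processed signal ran from 997 to 1435 over the 12 arrays, and 71.3% to 80.1% of spots were well above background. At most 1 spot per array was saturated. With 3 arrays per group, their number limits the precision.

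Processed signals were set to log2 and each array's 75th percentile over non-control spots was subtracted. Spots carrying the scanner's outlier flag were left out, and spots of the same probe were averaged. 109 probes with no usable spot on at least 1 array were dropped. A probe was kept if it was well above background, on at least 0.5 of its spots, on all 3 arrays of at least 1 group. For genes with several probes the brightest over the 12 arrays was used, which left 23851 genes. Gene names came from the files and were updated through the accession in a RefSeq gene table of assembly GRCh38.p14, where 27231 probes matched. A further 1942 probes took the symbol of another probe with the same name in the file, and 13232 kept the name in the file. All coordinates are probe positions on hg19, the build named in the file headers.

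The tests were made with limma 3.58.1 in R 4.3.3, and tables were handled with data.table (version 1.17.8), Python 3.11.15, pandas 2.3.3 and numpy 2.4.6. Plots were drawn with matplotlib 3.10.9. limma's lmFit and eBayes were fitted to all 12 arrays with the 6 aerosol and clean-air pairs as a fixed block, because the series design text refers each aerosol sample to the clean-air control of its day. The fit had 4 residual degrees of freedom. Contrasts were the beech effect, the pellet effect, the beech effect minus the pellet effect and the mean of both. Clean-air samples of the 2 fuels were compared with group means and no block. Adjusted p-values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05. As a check of the pairing, deviations from the group means were correlated between arrays: the same-numbered beech arrays gave r = 0.41, 0.22 and 0.50 over genes, and the same-numbered pellet arrays 0.08, -0.15 and -0.06. A fold against a group in which no array was well above background is given as a bound, taken against the lowest signal that was well above background on each array of that group, or the probe's own if higher. Such a bound holds for the main fit alone, not under other background handling.

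Before the data were examined, 25 gene lists with 471 entries were fixed, of which 439 entries matched a tested gene. They were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 25 lists, and again with an estimated correlation. limma's fry was run beside it. Camera compares a list with all other genes. At the preset correlation its p-value does not measure how a list as a whole varied between exposures. Metallothioneins, HSPA1A and HSPA1B, and the AKR1C genes are close paralogs whose probes may bind each other's transcripts, which was not tested. Members were also adjusted over the list alone. The rule for named genes was fixed at the same time. For beech and pellet it took up to 8 genes per direction that passed with the same sign in all 3 pairs, and up to 2 passing members per list or, for 4 lists, the member with the smallest p. It took up to 5 per direction for the difference and the mean, 3 per direction for clean air, and 5 by smallest p where none passed. CYP1A1, CYP1B1, TIPARP, NQO1, HMOX1, CXCL8 and IL6 were always given. Further list members are named as examples chosen after their values were seen.

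Alternatives were no replicate block, a random block, the slide as a block, a term for slide 2 beside the pairs, and arrays of 1 fuel only. Others were normexp background correction, quantile normalization, median scaling, the deposited values, no filter on dim probes, probes above background on all 12 arrays, the mean of a gene's probes, an intensity trend in the variance prior, a 1.5-fold minimum, and leaving out each replicate. Normexp was run with an offset of 50 on median rather than mean spot signals, since the files of slide 2 give only medians. A fit within slides, on the 10 arrays of slides 1 and 3, was added after the data were seen.

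The procedure was tested on simulated data made from the real pair levels and gene variances of the 23851 genes, with 500 changed genes per size over 10 simulations. For the beech comparison it recovered 2.40% of genes changed by 0.5 on the log2 scale, 67.6% at 1, 97.0% at 2 and 98.8% at 3. For the pellet comparison the shares were 3.60%, 64.4%, 96.6% and 99.4%. For the difference between fuels, with the beech effect changed, they were 0.00%, 18.4%, 89.2% and 96.6%. For the mean of both, with the beech effect changed, they were 0.20%, 19.4%, 86.4% and 96.4%. As only 1 fuel was changed, the true mean was 0.5 of each size. A change in both fuels was not simulated, so these shares do not give the recovery of a shared change of that size. Of the calls made, 6.91% were false for beech and 7.60% for pellet, and 5.33% to 6.75% for the difference and the mean, above the 5% set by the threshold. A list shifted by 0.5 in the changed fuel was called in 10 of 10 simulations of each comparison. The simulated noise was independent between genes, so the test does not cover the correlation between genes of a list. Each simulation held changed genes of every size. It gave up to 149 calls for beech and 152 for pellet, where the real comparisons gave 1 and 2. More calls loosen the Benjamini-Hochberg cut, so the shares recovered overstate what the real comparisons could find.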

Results

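The series measured how confluent A549 lung epithelial cells responded within 4 h to the complete aerosol of burning beech logs or of burning pellets. The 12 arrays gave log2 levels of 23851 genes in 4 groups of 3: beech aerosol, beech clean air, pellet aerosol and pellet clean air. Correlations between replicate arrays of a group, over genes, ran from 0.979 in beech aerosol to 0.995 in pellet aerosol. Changes are log2 differences between aerosol and clean air over 3 pairs, with standard errors from limma, and adjusted p-values cover all genes tested unless stated.

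Beech aerosol was compared with the clean air of the same exposures to ask which transcripts the log-wood aerosol changed. CYP2C18, a cytochrome P450 of the CYP2C family, fell by 2.51 ± 0.16 (SE, 3 pairs) on the log2 scale, 5.70-fold lower, in 3 of 3 pairs (adjusted p = 0.0405). Its probe lies on chromosome 10 from 96495397 to 96495456. It was the only gene of 23851 to pass in the limma fit, with 0 genes higher. At an unadjusted p below 0.05 there were 2557 genes, 1005 higher and 1552 lower, where 1193 would come by chance.

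Immediate early genes, which encode short-lived transcription factors and feedback regulators induced within minutes of a stimulus, were higher after beech aerosol in 21 of 22 measured members (median 0.65). The list rose against all other genes by camera (adjusted p = 1.08e-12), but not with allowance for how its members vary together (adjusted p = 0.923 with an estimated correlation). Of its members 0 passed over all genes, and 10 rose adjusted over the list alone. Examples were EGR1 at 2.42 ± 0.44, EGR2 at 2.69 ± 0.65, FOSB at 2.42 ± 0.60 and FOSL1 at 0.90 ± 0.16, all in 3 of 3 pairs. NF-kB and inflammatory genes were higher in 19 of 19 members (median 0.53, adjusted p = 6.27e-09; adjusted p = 0.923 with an estimated correlation). There 0 passed over all genes and 3 rose adjusted over the list alone. These were NFKB2, an NF-kB subunit (0.96 ± 0.16), the neutrophil chemokine CXCL8 (1.43 ± 0.30) and TNFAIP3, a feedback inhibitor of NF-kB (1.17 ± 0.31), each in 3 of 3 pairs. The cytokine IL6 stood at 0.95 ± 0.29 and did not pass (adjusted p = 0.329), and at 0.47 without replicate 1.

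The median change of the immediate early list lay between 0.18 and 1.25 in single pairs and that of the NF-kB list between 0.20 and 1.32, with replicate 1 highest in both. Without replicate 1 the mean change of the immediate early list was 0.46 against 0.93, and that of the NF-kB list 0.28 against 0.59. Without it EGR2 stood at 1.63, FOSB at 1.39, CXCL8 at 0.94 and TNFAIP3 at 0.69. Within slide 3, and equally with the slide as a block, the medians were 0.42 (adjusted p = 0.0021) and 0.51 (adjusted p = 0.000153). Over all alternatives the adjusted p ran from 8.65e-18 to 0.923 for immediate early genes and from 6.34e-11 to 0.923 for NF-kB genes.

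Genes of the xenobiotic and oxidant responses did not pass after beech aerosol. CYP1A1, the classical target of the aryl hydrocarbon receptor (AhR), stood at 1.56 ± 0.59, higher in 2 of 3 pairs (adjusted p = 0.425), and at 0.86 without replicate 1 and 2.52 without replicate 3. CYP1B1 stood at 0.05 ± 0.29 and TIPARP at 0.32 ± 0.36, both AhR targets, and at -0.34 and -0.21 without replicate 1. EREG at 0.59 ± 0.18 was the member of that list with the smallest p (adjusted p = 0.341), and stood at 0.32 without replicate 1. The NRF2 targets HMOX1 (-0.65 ± 0.16, lower in 3 of 3 pairs, adjusted p = 0.257) and NQO1 (-0.14 ± 0.12) did not pass, and the NRF2 list had a median of -0.05 (adjusted p = 0.278). SLC39A10, a zinc importer, had a value of -0.28 ± 0.16, and of -0.13 without replicate 2 and -0.44 without replicate 3. The single call was lost without replicate 1, without replicate 2 and without replicate 3 (0 genes in limma each time, with 1851 to 2401 at an unadjusted p below 0.05), and CYP2C18 then had adjusted p-values from 0.144 to 0.44. It was also lost with the slide as a block and within slide 3 (-2.01, adjusted p = 0.968) and without the pairs (adjusted p = 0.54), and over all alternatives its adjusted p ran from 0.00489 to 0.968, with 0 to 34 genes passing and estimates of CYP2C18 from -2.68 to -1.42, the last with normexp.

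**Figure D1:**
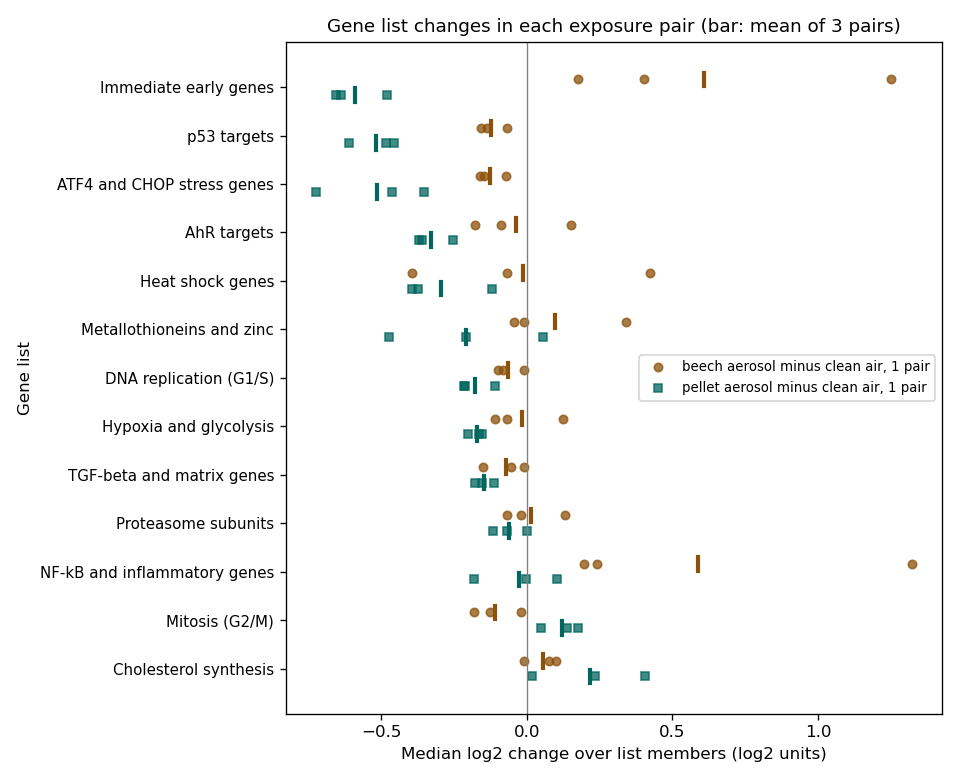
Median log2 change over the members of each gene list (horizontal axis, log2 units) in each exposure pair, for the 13 lists (vertical axis) that passed camera at the preset correlation in beech or pellet. Circles are beech pairs, squares are pellet pairs and bars are means of 3 pairs; immediate early genes lie from 0.18 to 1.25 in the beech pairs and from -0.65 to -0.48 in the pellet pairs.

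Pellet aerosol was compared with its own clean air in the same way. CHRM1, the muscarinic acetylcholine receptor M1, fell by 2.78 ± 0.16 (SE, 3 pairs), 6.86-fold lower, in 3 of 3 pairs (adjusted p = 0.0199). C1QTNF3, a secreted C1q and TNF related protein, rose in 3 of 3 pairs by 2.04 ± 0.14 (adjusted p = 0.0302). It was not well above background on any pellet clean-air array, so the change is at least 3.90-fold in the main fit. With normexp it was 0.31 on the log2 scale. The CHRM1 probe lies on chromosome 11 from 62676155 to 62676214 and the C1QTNF3 probe on chromosome 5 from 34020604 to 34020663. These 2 genes were the whole count in limma, and 2592 genes had an unadjusted p below 0.05 (1506 higher, 1086 lower, 1193 by chance).

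Targets of p53, which arrest the cell cycle or promote cell death, were lower after pellet aerosol in 22 of 23 members (median -0.48). The list fell by camera (adjusted p = 5.77e-16) and also with an estimated correlation (adjusted p = 0.0345), and by fry (adjusted p = 0.000765). Of its members 0 passed over all genes, and 14 fell adjusted over the list alone. They included the cell cycle inhibitor CDKN1A at -1.16 ± 0.14, GADD45A at -1.23 ± 0.16, the pro-apoptotic BBC3 at -0.94 ± 0.13 and the exonuclease AEN at -0.81 ± 0.09, each lower in 3 of 3 pairs. The negative regulator of p53, MDM2, stood at -0.88 ± 0.22 and also fell adjusted over the list alone (adjusted p = 0.0141).

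ATF4 and CHOP stress genes, the transcriptional arm of the integrated stress response, were lower in 19 of 19 members (median -0.45, adjusted p = 5.77e-16; adjusted p = 0.107 with an estimated correlation). Here 0 passed over all genes and 8 fell adjusted over the list alone, among them STC2 at -1.68 ± 0.20, ATF3 at -1.80 ± 0.38, CHAC1 at -1.95 ± 0.41 and PPP1R15A at -1.44 ± 0.31. Immediate early genes were lower in 21 of 22 members (median -0.63, adjusted p = 3.52e-11; adjusted p = 0.4 with an estimated correlation). Of these 0 passed over all genes and 5 fell adjusted over the list alone: CCN1 at -1.06 ± 0.16, JUN at -1.17 ± 0.20, KLF2 at -1.10 ± 0.20, KLF6 at -0.82 ± 0.19 and FOSL1 at -0.64 ± 0.16. Heat shock genes were lower in 18 of 18 members (median -0.33, adjusted p = 2.63e-07; adjusted p = 0.408 with an estimated correlation). With 0 passing over all genes, the small heat shock protein HSPB8 (-1.10 ± 0.13) and HSPA4L (-0.58 ± 0.13) fell adjusted over the list alone.

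Of the hypoxia and glycolysis genes, 17 of 20 were lower after pellet aerosol (median -0.15, adjusted p = 3.24e-05; adjusted p = 0.237 with an estimated correlation). 0 of them passed over all genes and 5 fell adjusted over the list alone, including ADM at -1.15 ± 0.18 and the angiogenic factor VEGFA at -0.89 ± 0.16. TGF-beta and matrix genes were lower in 16 of 21 (median -0.11, adjusted p = 0.000301; adjusted p = 0.113 with an estimated correlation). 0 passed over all genes and 4 fell adjusted over the list alone, among them SMAD7 (-0.79 ± 0.11), CCN2 (-0.79 ± 0.15) and ANKRD1 (-0.78 ± 0.18). Metallothioneins and zinc genes were lower in 8 of 9 (median -0.21, adjusted p = 0.00141; adjusted p = 0.4 with an estimated correlation). With 0 passing over all genes, the zinc exporter SLC30A1 (-0.91 ± 0.12, lower in 3 of 3 pairs) was the only member to fall adjusted over the list alone.

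AhR targets were lower in 8 of 10 members after pellet aerosol (median -0.32, adjusted p = 0.00412; adjusted p = 0.184 with an estimated correlation), with 0 members passing over all genes and 0 adjusted over the list alone in limma. CYP1A1 stood at -1.93 ± 0.59, lower in 3 of 3 pairs (adjusted p = 0.309). The AhR repressor AHRR (-0.81 ± 0.24), TIPARP (-0.77 ± 0.36) and CYP1B1 (-0.52 ± 0.29) did not pass. DNA replication genes were lower in 18 of 21 (median -0.12, adjusted p = 0.000312; adjusted p = 0.302 with an estimated correlation). Proteasome subunits were lower in 23 of 25 by small amounts (median -0.04, adjusted p = 0.0466; adjusted p = 0.63 with an estimated correlation), a call lost under 11 of 16 alternatives. Cholesterol synthesis genes rose as a list, with 17 of 20 members higher (median 0.17, adjusted p = 0.00734; adjusted p = 0.432 with an estimated correlation), and so did mitosis genes (17 of 21 higher, median 0.13, adjusted p = 0.0156; adjusted p = 0.4 with an estimated correlation). None of these 4 lists had a member that passed, over all genes or adjusted over the list alone. NF-kB and inflammatory genes did not pass (median -0.11, adjusted p = 0.334). CXCL8 stood at 0.13 ± 0.30, IL6 at -0.23 ± 0.29 and IL11, the member with the smallest p, at -0.83 ± 0.19. The NRF2 list did not pass (median -0.03, adjusted p = 0.185), with HMOX1 at -0.58 ± 0.16 (adjusted p = 0.265) and NQO1 at -0.08 ± 0.12.

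Within slide 1, and equally with the slide as a block, the pellet medians were -0.57 for p53 targets, -0.48 for ATF4 and CHOP genes, -0.70 for immediate early genes and -0.38 for heat shock genes, with adjusted p-values of 2.64e-14, 1.9e-15, 2.04e-06 and 8.35e-09, and highest adjusted p over alternatives of 0.0345, 0.107, 0.4 and 0.408. The other medians there were -0.11 for hypoxia, -0.17 for TGF-beta, -0.17 for DNA replication, -0.40 for AhR, 0.35 for cholesterol and 0.15 for mitosis genes (adjusted p = 5.78e-05, 0.000216, 7.21e-05, 0.00289, 0.000336 and 0.0417), while metallothioneins (-0.06, adjusted p = 0.194) and proteasome subunits (-0.06, adjusted p = 0.0561) did not pass. CHRM1 (-2.65, adjusted p = 0.308) and C1QTNF3 (2.27, adjusted p = 0.261) did not pass there. Their calls were also lost without the pairs (adjusted p = 0.181 and 0.179) and without replicate 1, 2 or 3, when limma gave 0 genes, with 1951 to 2611 at an unadjusted p below 0.05, and adjusted p was 0.131, 0.3 and 0.198 for each of them. With normexp C1QTNF3 stood at 0.31, and over alternatives the adjusted p ran from 0.000761 to 0.308 for CHRM1 and from 0.0135 to 0.523 for C1QTNF3, with 0 to 82 genes passing. The AhR list was lost without replicate 1 (adjusted p = 0.129), the mean change of the metallothionein list was -0.16 without replicate 3 against -0.25, the cholesterol list was lost without replicate 2 (0.0908) and without replicate 3 (0.578), the mitosis list without replicate 2 (0.17) and without replicate 3 (0.364), and the proteasome list without replicate 1 (0.176) and without replicate 2 (0.189). The cholesterol list was also lost without the pairs (0.0853), and with a term for slide 2 the cholesterol (0.0717), mitosis (0.0713) and proteasome (0.192) lists were lost.

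**Figure D2:**
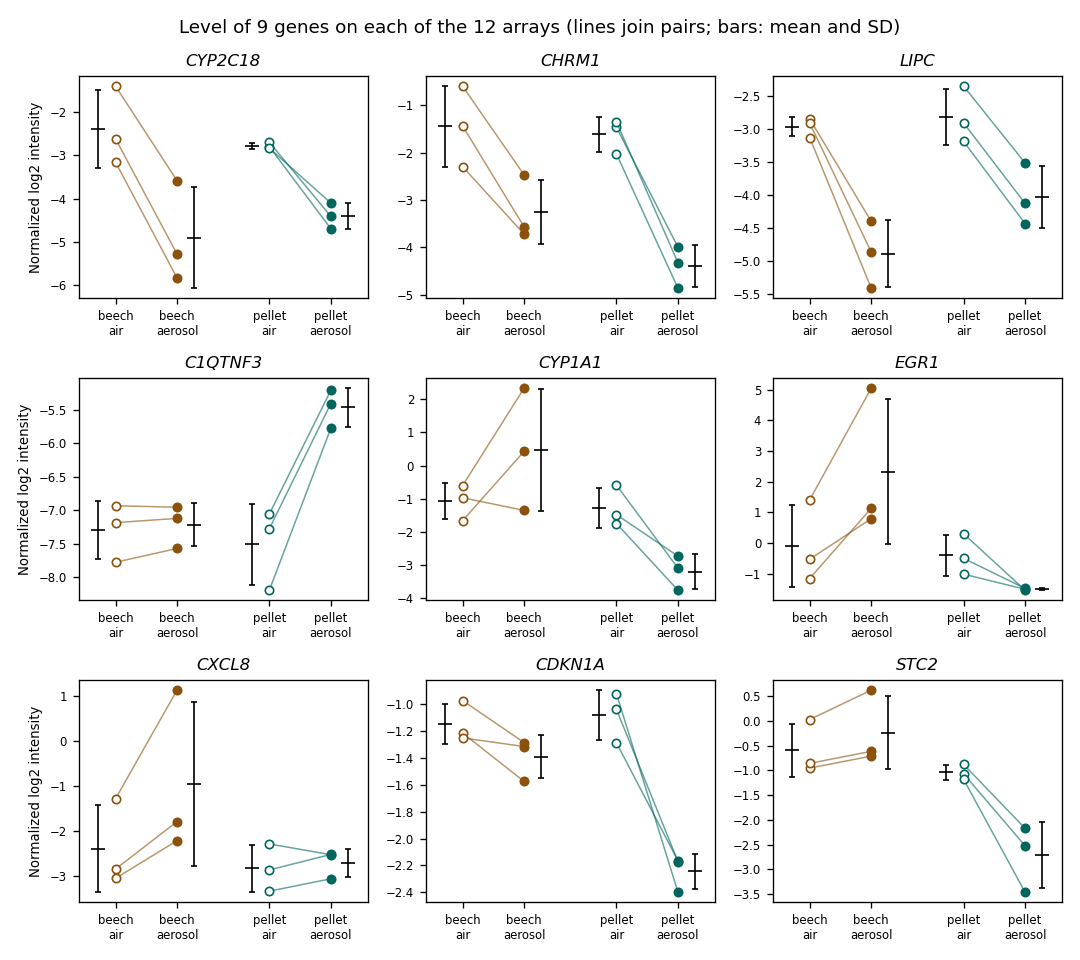
Normalized log2 intensity (vertical axes) of 9 genes on the 12 arrays, by group (horizontal axes). Open circles are clean air, filled circles are aerosol, lines join arrays of the same pair, and black bars show the mean and SD of 3 arrays; CHRM1 is lower with aerosol in all 6 pairs, while CYP1A1 is lower in the 3 pellet pairs and higher in 2 of the 3 beech pairs.

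Whether the fuels differed was tested on the beech effect minus the pellet effect. Immediate early genes separated the fuels most: the difference had a median of 1.35, with 21 of 22 members higher for beech (adjusted p = 9.93e-24; adjusted p = 0.214 with an estimated correlation), and 14 passed adjusted over the list alone against 0 over all genes. Examples were EGR1 at 3.52 ± 0.62, FOS at 2.77 ± 0.79 (1.79 without beech replicate 1) and JUN at 2.15 ± 0.28. For p53 targets the difference had a median of 0.31 (adjusted p = 4.95e-09; adjusted p = 0.103 with an estimated correlation) and 8 members passed adjusted over the list alone, 0 over all genes, among them GADD45A at 1.51 ± 0.23. NF-kB genes had a median difference of 0.63 (adjusted p = 1.13e-08; adjusted p = 0.28 with an estimated correlation), with 0 members passing over all genes and 0 adjusted over the list alone in limma, and its mean difference was 0.33 without beech replicate 1 against 0.64. In the AhR list CYP1A1 (3.48 ± 0.83) and EREG (1.02 ± 0.26) passed adjusted over the list alone and 0 over all genes.

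In all, 10 of the 25 lists differed between the fuels at the preset correlation, 0 with an estimated correlation, and 1, the p53 targets, by fry (adjusted p = 0.00953). No single gene passed in limma over all genes (0 of 23851, with 1929 at an unadjusted p below 0.05 and 1193 by chance). The 5 genes with the smallest p were SOX6 (adjusted p = 0.214), C1QTNF3, JUN, CCN2 at 1.53 ± 0.21 and RHOB at 1.68 ± 0.23, the last 4 with adjusted p = 0.307. SOX6 was not well above background in beech aerosol. Its beech change lay at least 3.63-fold below its pellet change in the main fit, but the log2 difference ran from -1.92 to -0.32 over alternatives. C1QTNF3 was well above background in pellet aerosol alone, so that no size is given for it. CXCL8 at 1.31 ± 0.43, IL6 at 1.17 ± 0.41, TIPARP at 1.09 ± 0.51, CYP1B1 at 0.57 ± 0.41, NQO1 at -0.06 ± 0.17 and HMOX1 at -0.07 ± 0.22 did not pass. Without beech replicate 1 CXCL8 stood at 0.82, IL6 at 0.69, TIPARP at 0.56 and CYP1B1 at 0.18, the last at 1.01 without beech replicate 3. The sign of NQO1 turned under median scaling (0.03) and without pellet replicate 3 (0.07), and that of HMOX1 under median scaling (0.02), without beech replicate 1 (0.09) and without pellet replicate 2 (0.04).

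Within slides, and equally with the slide as a block, 8 lists differed between the fuels: immediate early genes (median 1.20, adjusted p = 4.45e-11), p53 targets (0.38, 9.69e-10), NF-kB genes (0.58, 6.01e-06), ATF4 and CHOP genes (0.23, 1.7e-06), heat shock genes (0.41, 2.42e-05), mitosis genes (-0.25, 7.03e-05), hypoxia genes (0.23, 0.000111) and AhR targets (0.28, 0.0111). Metallothioneins (-0.04, adjusted p = 0.719) and TGF-beta genes (0.07, adjusted p = 0.204) did not. None of these lists passed by camera with an estimated correlation on the pairs (adjusted p from 0.103 to 0.546). The AhR list was lost without pellet replicate 1 (adjusted p = 0.167), the heat shock list without beech replicate 1 (0.147, mean difference 0.13 against 0.42, and 0.65 without beech replicate 3) and without pellet replicate 1 (0.0845), and the TGF-beta list without beech replicate 2 (0.0543), without pellet replicate 1 (0.123) and without the pairs (0.075). The mean difference of the hypoxia list was 0.22 without beech replicate 1 against 0.35.

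The mean of both effects, over 6 pairs, was tested for changes that hold on average. 35 genes fell and 1 rose. The largest falls were in CHRM1 (-2.29 ± 0.11, 4.90-fold lower, adjusted p = 0.0072), CYP2C18 (-2.07 ± 0.11, adjusted p = 0.00742), the hepatic lipase gene LIPC (-1.57 ± 0.10, adjusted p = 0.0158), the collagen galactosyltransferase COLGALT2 (-1.52 ± 0.15, adjusted p = 0.0311) and GARIN1B (-1.47 ± 0.14, adjusted p = 0.0298), each lower in 6 of 6 pairs. COLGALT2 was well above background on only 1 of the 3 beech aerosol arrays, so the size of its fall is less certain. C1QTNF3 was the gene that rose, but it was well above background in pellet aerosol alone, so no size is given for the mean. Falls of the remaining genes, chosen after their values were seen, included the cytokine IL13 (-1.24), the thyroglobulin gene TG (-1.04), the endothelin EDN2 (-0.90) and the phosphodiesterase PDE2A (-0.90).

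Among the lists, ATF4 and CHOP genes were lower in the mean in 19 of 19 members (median -0.31, adjusted p = 1.29e-10; adjusted p = 0.22 with an estimated correlation) and p53 targets in 21 of 23 (median -0.32, adjusted p = 1.29e-10; adjusted p = 0.076 with an estimated correlation). With 0 passing over all genes, 10 and 11 members fell adjusted over the list alone, among them NUPR1 at -1.10 ± 0.15 and CDKN1A at -0.70 ± 0.10. NUPR1 was also the only ATF4 and CHOP gene that fell after beech alone adjusted over the list alone (-1.12 ± 0.21). Heat shock, DNA replication and TGF-beta lists fell and NF-kB and cholesterol lists rose (adjusted p = 0.000407, 0.00409, 0.0137, 0.00461 and 0.0137; adjusted p = 0.614, 0.515, 0.312, 0.614 and 0.614 with an estimated correlation). Of these lists NF-kB genes had medians of 0.53 after beech and -0.11 after pellet, so their mean does not describe a shared change. Heat shock genes had -0.04 and -0.33, but the beech median was -0.26 without replicate 1, so a shared fall is left open. ATF4 and CHOP, p53, DNA replication, TGF-beta and cholesterol lists passed for pellet but not for beech. Of these, ATF4 and CHOP (adjusted p = 6.21e-07), p53 (4.95e-09) and TGF-beta genes (0.014) also differed between the fuels by camera. None did with an estimated correlation. For ATF4 and CHOP, p53 and TGF-beta genes the mean thus does not show a change of like size in both fuels. Their beech medians were negative in each of the 3 pairs but did not pass. For DNA replication and cholesterol genes, which did not differ between the fuels, a shared change is left open. With the slide as a block both lists passed camera in both fuels. DNA replication stood at -0.18 after beech and -0.17 after pellet, and cholesterol at 0.19 and 0.35. Immediate early genes, which went opposite ways, had a mean-effect median of 0.06 (adjusted p = 0.853). In the NRF2 list HMOX1 fell adjusted over the list alone (-0.61 ± 0.11, adjusted p = 0.0242), lower in 6 of 6 pairs, and the list itself did not pass (adjusted p = 0.0623). The count of 36 genes became 5 without the pairs, 0 within slides and with the slide as a block (1895 at an unadjusted p below 0.05), and 0 to 237 over all alternatives. Leaving out beech replicate 1, 2 or 3 gave 1, 2 and 5 genes, and leaving out pellet replicate 1, 2 or 3 gave 0, 0 and 2 (2395 and 2493 at an unadjusted p below 0.05 where limma gave 0).

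Within slides CHRM1 stood at -2.02, CYP2C18 at -1.84, LIPC at -1.44, COLGALT2 at -1.46 and GARIN1B at -1.29 (adjusted p = 0.2, 0.315, 0.2, 0.294 and 0.498). CHRM1 was lost without pellet replicate 1 (adjusted p = 0.0522) and without pellet replicate 2 (0.0923), and CYP2C18 also without beech replicate 1 (0.0631) and 2 (0.0707), with 0.0624 and 0.0923 for the pellet replicates. LIPC passed only without beech replicate 2 (0.0373), and COLGALT2 and GARIN1B only without beech replicate 3 (0.0277 each), with adjusted p-values up to 0.173, 0.192 and 0.176 otherwise. Over all alternatives the adjusted p ran from 0.000191 to 0.2 for CHRM1, from 0.000632 to 0.315 for CYP2C18, from 0.00194 to 0.2 for LIPC, from 0.0126 to 0.294 for COLGALT2 and from 0.00258 to 0.498 for GARIN1B. With normexp CYP2C18 stood at -1.22, LIPC at -0.89 and COLGALT2 at -0.56. Lists within slides had medians of -0.37 for ATF4 and CHOP genes, -0.27 for p53 targets, -0.21 for heat shock, -0.17 for DNA replication, 0.27 for cholesterol and -0.13 for TGF-beta genes (adjusted p = 1.59e-10, 1.32e-08, 3.3e-05, 3.8e-06, 2.51e-05 and 0.000382), while NF-kB genes (0.19, adjusted p = 0.121) did not pass. The heat shock list was lost without beech replicate 3 (adjusted p = 0.0836, mean change -0.06 against -0.17, and -0.32 without beech replicate 1), NF-kB without pellet replicate 3 (0.0959; without beech replicate 1 its mean change was 0.12 against 0.27), cholesterol without beech replicate 2 (0.0552) and pellet replicates 2 (0.0627) and 3 (0.338), and TGF-beta without beech replicate 3 (0.0599) and pellet replicates 1 (0.0738) and 2 (0.0508). Cholesterol was also lost without the pairs (0.0979) and with a term for slide 2 (0.162). With an estimated correlation on the pairs none of these lists passed.

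Across the 23851 genes the beech and pellet effects correlated weakly, with r = 0.16, rho = 0.175 and a covariance of 0.0121; genes are not independent replicates. The fuels had separate controls. Signs matched in 56.6% of genes. At an unadjusted p below 0.05 in both, 343 genes were lower in both where independent lists would share 70.7, and 160 were higher in both against 63.5. Another 158 went opposite ways, for which no expected count was made. The lists are not independent, because both fuels' p-values use the same estimate of each gene's spread. Clean-air replicate 3 of both fuels also shared slide 2. The excess over independent lists thus does not measure a shared response. Single beech pairs against single pellet pairs gave r from -0.02 to 0.14 (9 values, SD 0.06). With each fuel compared within its slide r was 0.19, with a term for slide 2 it was 0.31, without the filter on dim probes 0.09, without beech replicate 3 also 0.09, and without replicate 3 of both fuels 0.10.

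The clean-air arrays of both fuels were compared as a background for these differences, since they hold day, passage and slide. No gene passed in limma (0 of 23851, with 2071 at an unadjusted p below 0.05, 1809 of them higher in beech clean air). The genes with the smallest p were CIDEB (1.30 ± 0.18), LCE6A (0.81 ± 0.12), CCDC177 (1.36 ± 0.22), ZNF582 and DEFB123, all with adjusted p = 0.202. ZNF582 was not well above background in beech clean air, at least 2.29-fold lower there in the main fit (log2 from -1.48 to -0.21 over alternatives). DEFB123 was not well above background in pellet clean air, at least 2.97-fold lower there in the main fit (log2 difference from 0.39 to 2.01 over alternatives). The median of all genes was 0.06 higher in beech clean air. Against that, 9 lists were lower in beech clean air by camera and 0 with an estimated correlation. Mitosis genes led with a median of -0.18 and 20 of 21 members lower (adjusted p = 2.28e-10; adjusted p = 0.163 with an estimated correlation), and p53 targets followed with -0.08 (adjusted p = 0.0123; adjusted p = 0.163 with an estimated correlation). 10 genes passed with the slide as a block, and 29 without beech clean-air replicate 3, 27 of them higher in beech clean air.

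The remaining lists did not pass for beech or for pellet with the pairs as a block. Their beech and pellet medians were 0.06 and -0.01 for the mitochondrial respiratory chain, -0.01 and -0.04 for endoplasmic reticulum chaperones, -0.02 and -0.03 for autophagy and lysosome genes, -0.05 and 0.04 for DNA repair, 0.04 and 0.05 for interferon-stimulated genes, -0.04 and 0.04 for replication-dependent histones, and 0.01 and -0.03 for housekeeping genes. Cell type markers did not pass either: alveolar epithelial markers stood at -0.01 and 0.04, airway and mucus markers at 0.03 and 0.05, leukocyte and macrophage markers at -0.04 and -0.10, and fibroblast and endothelial markers, with 3 measured members, at 0.05 and 0.10. The smallest adjusted p among these lists was 0.0568, for the chaperones after pellet aerosol. For beech, heat shock genes (-0.04), hypoxia genes (0.05), metallothioneins (0.10), AhR targets (0.04), ATF4 and CHOP genes (-0.16) and p53 targets (-0.16) did not pass. Neither did beech cholesterol (0.06), mitosis (-0.07), DNA replication (-0.06), TGF-beta (-0.08) and proteasome genes (0.00). With the slide as a block, and within slide 3, 4 further beech lists passed: DNA replication (-0.18, adjusted p = 0.00115), cholesterol (0.19, 0.0021), mitosis (-0.14, 0.0185) and the mitochondrial respiratory chain (0.08, 0.0408), none of which passed with an estimated correlation on the pairs (adjusted p = 0.923 each). Mitosis also passed without the pairs (0.0366), with normexp (0.0448) and without replicate 1 (0.0084), and the respiratory chain with a term for slide 2 (0.0332) and without replicate 3 (0.00439). Heat shock genes passed as lower without replicate 1 (0.000126), ATF4 and CHOP genes without the pairs (0.0366) and with normexp (0.031), and NRF2 targets with normexp (0.031). None of them passed with an estimated correlation on the pairs either (adjusted p = 0.923 each). Median and mean had opposite signs in 4 beech, 1 pellet, 5 mean and 2 clean-air lists, and the direction of the test opposed the median in 2, 1, 3 and 8, with 1 more in the difference; 0 of these lists passed.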

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

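The tests of slides, scaling, control levels, replicate 1 and handling in this part were chosen after the results were seen, while the counts of other splits were set before theirs.

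10 lists differed between the fuels by camera on the difference itself. The median of beech change minus pellet change was 1.3471 for immediate early genes, 0.3098 for p53 targets, 0.627 for NF-kB and inflammatory genes, 0.1821 for ATF4 and CHOP stress genes, 0.1638 for hypoxia and glycolysis genes and 0.3647 for heat shock genes. It was -0.2124 for mitosis genes, 0.3159 for metallothioneins and zinc genes, 0.145 for AhR targets and 0.0533 for TGF-beta and matrix genes. With an estimated correlation 0 of the 10 passed, with adjusted p-values from 0.103 to 0.546. Of the 10 ways to part the 6 pairs into groups of 3, 3 gave as many as 10 lists and the highest other gave 12, and all 10 gave as many genes as the real 0, the highest other being 0. With 10 splits no share under 0.05 is possible.

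The first pattern is the fall of p53, ATF4 and immediate early lists after pellet aerosol, where 62 of 64 members were lower (median -0.52). A difference between slides is argued against by a median of -0.5949 within slide 1, where all 6 array pairs lay between -0.67 and -0.51. A constant per array cannot move the median relative to all genes, so median scaling and the deposited values (-0.5438 each) tested nothing. Quantile normalization could move it, and its median of -0.535 argues against scaling. The value nearest to 0 was -0.4828, with normexp, which is a background correction. Controls raised in pellet alone are argued against by pellet aerosol lying 0.51 below beech clean air (-0.5138, all 9 array pairs between -0.74 and -0.36) while pellet clean air lay 0.04 above it. That comparison also holds day and slide, and its 9 array pairs reuse 3 arrays per group. Controls raised in both fuels would give the same values, so that case is not tested. The real split gave 12 lists and the highest of the other 9 splits gave 9 (1 of 10 as large), with 4 the highest among those parting all pairs; with 10 splits no share under 0.05 is possible. A lower activity of these programmes under pellet aerosol may remain as a hypothesis, beside a technical or handling difference between the arms that recurred in each exposure, which was not tested.

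The second pattern is the rise of immediate early and NF-kB lists after beech aerosol, with 40 of 41 members higher (median 0.63) and pair medians of 1.28, 0.24 and 0.30 for replicates 1, 2 and 3. Replicate 1 as the whole cause was not settled. Without it the median was 0.2688, with 33 members higher. Both lists passed by camera (adjusted p = 1.25e-06 and 2.29e-05), but not with an estimated correlation on all pairs (0.923). The median lay above 2 SEs of 0.04, but that SE came from the spread between pellet pairs, and replicates 2 and 3 alone carried the value. Most of the size came from replicate 1. A difference between slides could enter only the pair of replicate 3 (0.30). The pairs of replicates 1 and 2 lie within slide 3, so it cannot account for their values. Whether the lists rise without replicate 3 was not settled. Those 2 pairs gave a median of 0.7524, but at 1.28 and 0.24 they lay too far apart (SE 0.52) for it to exceed 2 SEs. Of the 6 array pairs within that slide 4 were higher, from -0.42 to 1.81, although both lists passed there. These bounds were changed after the values were seen: of 4 tried for replicate 1, 3 argued against it and 1, with the SD of 0.22 between clean-air arrays, did not and was dropped because that spread lies between exposures; of 5 tried for slides, 3 argued against them, among them 1 with the SE of 0.04. The 6 clean-air arrays ranged over 0.6132, but that spread lies between exposures and the change within them, so it says nothing on handling that differed between the arms, which stays open.

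For lists, 6 of 10 splits of the beech arrays gave as many as the real 2 and the highest other gave 7. For single genes the splits were as few. In beech, 3 of 10 splits gave as many as the real 1 gene. The highest other gave 13, in both splits that part only replicate 1, which points to a structure of these samples in which replicate 1 stands apart. With the pairs as a block, a split that parts 1 pair compares aerosol with clean air in that pair alone. Such a split is no random grouping, so a share that counts it says nothing on chance. Splits parting all pairs gave 0 otherwise. In pellet, 5 of 10 gave as many as the real 2 and the highest other gave 4, with 0 among the others that part all pairs. The other splits with as many each parted 1 pair alone. For clean air against clean air, all 10 splits gave as many as the real 0 genes, the highest other being 0, and 1 of 10 gave as many as the real 9 lists, the highest other being 7. With 10 splits no share under 0.05 is possible for any of these.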

How the results depend on the processing

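The fit within slides was chosen after the data were seen, and the other settings before. Of the lists that passed, p53 targets after pellet kept its call in 16 of 16 alternatives (adjusted p from 2.7e-20 to 0.0345). The beech immediate early and NF-kB lists and the pellet ATF4, immediate early, heat shock, hypoxia, DNA replication and TGF-beta lists each lost it only with an estimated correlation (15 of 16 kept). Over lists, 475 values kept direction and side of the threshold and 72 lost the call in the same direction. For named genes 691 values kept both, 77 lost the call, 5 gained it and 10 turned sign. The median of all genes under the scalings lay at most 0.0649 from 0. Signal over background limits faint genes: C1QTNF3 after pellet had estimates from 0.31 to 2.27.

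Pairing: without the replicate block beech gave 0 genes and 4 lists, pellet 1 gene, and the mean 5 genes; no other count of genes or lists past the threshold moved by over 1.5 times, but the genes at an unadjusted p below 0.05 fell to 1464 for beech, 1540 for pellet, 843 for the difference and 2092 for the mean. In beech each aerosol array correlated best with its own number, in pellet none did, so that the pellet arrays share a day by the design text alone. With a random block (correlation 0.252) pellet gave 18, the difference 1 and the mean 104 genes. The cause was not tested, beyond the added residual degrees of freedom.

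Slides: with the slide as a block, and within slide, beech, pellet and the mean gave 0 genes, beech gave 6 lists (DNA replication, cholesterol, mitosis and mitochondrial respiratory chain added), and clean air gave 10 genes with the block. Both fits give the same aerosol estimates, because slide 2 holds clean air only. With a term for slide 2 beside the replicate block pellet gave 0 genes, the mean 1, and the correlation of effects rose to 0.3064, where both fuels share the error of that term. On arrays of that fuel only, with fewer residual degrees of freedom, beech and pellet gave 0.

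Values: normexp gave 6 beech, 38 pellet and 88 mean genes, and 5 beech lists. Quantile normalization gave 0, 4 and 57. Median scaling gave 0 beech and 65 mean genes. The pellet split, 1 higher and 1 lower, became 2 and 36 with normexp, 2 and 2 with quantile and 1 and 2 with median scaling. Without the dim-probe filter, which tests more genes, beech, pellet and the mean gave 0 and the correlation was 0.0886. With probes above background on all 12 arrays the counts were 11, 24 and 91, and with an intensity trend 34, 82 and 237. With an estimated correlation the lists past the threshold were 0 for beech, 1 for pellet, 0 for the difference and 0 for the mean. The cause was not tested. Wherever limma gave 0 genes, 674 to 3184 had an unadjusted p below 0.05.

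Leaving out a replicate gave 0 to 0 genes for beech, for pellet and for the difference, 0 to 5 for the mean and 0 to 29 for clean air, where 29 came without beech clean-air replicate 3. Lists ranged from 2 to 4 for beech, 9 to 10 for pellet, 8 to 14 for the difference and 5 to 11 for the mean, and the correlation from 0.0895 to 0.1929. Where a pair is left out the 2 others carry that fuel and the spread is pooled over fuels.

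Signs that turned, all of genes that did not pass: CXCL8 after pellet was -0.1262 within slide and with the slide as a block. NQO1 in the difference was 0.0269 with median scaling and 0.0747 without pellet replicate 3. HMOX1 in the difference was 0.0177 with median scaling, 0.0926 without beech replicate 1 and 0.0392 without pellet replicate 2. After beech without replicate 1, CYP1B1 was -0.3378 and TIPARP -0.2107, and NQO1 after pellet was 0.0347 without replicate 2. Leaving out a replicate moved these from -0.3378 to 0.4848 (CYP1B1) and -0.2107 to 0.834 (TIPARP) after beech, from -0.2122 to 0.0347 (NQO1) after pellet, and from -0.1722 to 0.0747 (NQO1) and -0.2257 to 0.0926 (HMOX1) in the difference. The cause was not tested.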

Other observations

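The tests of slides and background and the count over splits parting all 6 pairs were chosen after the results were seen, while the test of upstream neighbours and the counts over 100 splits were set before theirs.

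Single members of some lists changed in the mean of both fuels or went opposite ways. Among interferon-stimulated genes, a list that did not pass for either fuel, HERC5 (-0.63 ± 0.13) and OAS2 (-0.68 ± 0.13) fell in the mean of both fuels adjusted over the list alone, while OAS1 (0.38 ± 0.08) and STAT2 (0.33 ± 0.10) rose, with 0 of them passing over all genes. OAS2 and OAS1 encode related enzymes that sense double-stranded RNA, and STAT2 carries the interferon signal. In the autophagy list WIPI1 rose (0.49 ± 0.08) and GPNMB fell (-0.55 ± 0.13) adjusted over the list alone, with 0 passing over all genes. In the hypoxia list the fuels parted; the list passed for pellet and for the difference but not for beech, and neither call held with allowance for correlation (adjusted p = 0.237 for pellet and adjusted p = 0.214 for the difference with an estimated correlation). The lipase inhibitor ANGPTL4 rose after beech (0.69 ± 0.13) and fell after pellet (-0.47 ± 0.13), and its difference of 1.16 ± 0.18 passed adjusted over the list alone (adjusted p = 0.009). PFKFB3, which drives glycolysis, fell after both (-0.40 ± 0.10 and -0.53 ± 0.10) adjusted over the list alone.

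The 35 genes that fell in the mean of both fuels include CHRM1, LIPC, TG and IL13 and were not tested for a common function. Of the 35, 33 were well above background on all 12 arrays, and their median level lay at the 40.4th percentile of tested genes. A probe of 21258 of the 23851 genes met that bar too, so it does not settle noise near background. With normexp 27 of the 36 calls were kept. The changes shrank there, with CYP2C18 at -1.22 against -2.07, LIPC at -0.89 against -1.57 and COLGALT2 at -0.56 against -1.52. A difference between slides could enter only the pairs of replicate 3, where the 35 genes had a median change of -0.88. It cannot account for their fall in the other pairs, which lie within slides (median -0.96). The 35 had been called from a fit that holds these pairs, so that median does not show that the fall would recur. Over all genes, the effects of both fuels in the pairs within slides correlated by 0.0973, below 2 SDs (SD 0.06). A shared response without replicate 3 is thus left open. With arrays not paired the correlation within slides was 0.1892. These 3 tests were tried after the values were seen. Within slides limma gave 0 genes (1895 at an unadjusted p below 0.05), and the median change of the 35 went from -0.93 (median SE 0.09) to -0.81 (median SE 0.23). That fit leaves out both the pairs and 2 arrays, which were not told apart, and without the pairs alone 5 genes passed. A hypothesis was that these transcripts may arise from transcription running on from an upstream neighbour: 10 of the 35 had a gene at or above the 75th percentile of level within 100 kb upstream on the same strand, against a median of 7 in 10000 lists matched on level (one-sided permutation p = 0.161) and 9 with such a gene downstream. That share, 28.6% (exact binomial 95% interval 14.6% to 46.3%), is below what the hypothesis needs if it is to cover most of them, though neighbours without a probe were not counted.

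Other splits of the same arrays bear on this pattern. Of 100 splits of the arrays within fuels, 1 gave as many as 36 genes, the real one, and the highest other gave 9, but 82 of these splits leave some pairs unparted. Over all 32 splits that part all 6 pairs, 1 gave as many as 36 genes, the real one, and the highest other gave 0. That set was chosen after the count was seen, and 1 of 32 is the smallest share it can give. The count was thus rare among splits, but chance is not excluded. For the number of lists in the mean, 38 of 100 splits gave as many as the real 7, and so did 10 of the 32 that part all pairs, with 14 the highest other in each case, so chance cannot be excluded there.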
